A study of Homo sapiens with 8 samples.

How the data were processed

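RNA of MCF-7 cells, an established human breast cancer line that expresses the estrogen receptor, was measured on 8 Affymetrix human expression arrays of 54675 probe sets. Per the labels, 4 arrays came from cells carrying FAKsiRNA, 2 from vector control cells, 1 from siRNA control cells and 1 from MCF-7 cells for which no construct is named, called plain MCF-7 here. The labels describe the siRNA lines as stable and hygromycin-resistant, and the design text names a pair of FAK siRNAs and a control siRNA against luciferase, without saying which array carries which FAK siRNA. Per the labels' protocols, 4 arrays (2 FAKsiRNA, 1 plain MCF-7 and 1 vector control) were labelled by the standard Affymetrix protocol from 100 ng of total RNA. The other 4 (2 FAKsiRNA, 1 siRNA control and 1 vector control) were labelled with a MessageAmpII amplification kit from 1 ug. No label says whether arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

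The deposited values are log2 expression levels. Per the submitters' processing notes they were made with RMA, which corrects background, normalizes quantiles and summarises the probes of each probe set; its version, and whether both labelling protocols were normalized in 1 run, are not given in the sources used here. The values ran from 1.47 to 14.7 log2, with array medians between 5.59 and 5.70 log2. They were used as deposited, with no further scaling and no filter on low values. The number of arrays limits the precision. On RMA values, which hold no detection call, a probe set near the floor understates differences.

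Probe sets were named through the platform's gene annotation. Of the 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were unnamed there. Gene identifiers of 41043 of the 1-symbol probe sets matched the RefSeq gene table of assembly GRCh38.p14, used for names only, and 0 symbols changed. Each gene was represented by its 1-symbol probe set with the highest mean over the 8 arrays, which gave 19775 genes. The files name no genome build, so no coordinates are given.

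Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. FAKsiRNA against all controls was fitted as 2 arms of 4 arrays. The other 5 comparisons came from a fit of the 4 groups over all 8 arrays, which share 1 estimate of the spread because 2 of the groups have 1 array, so that a lone array is assumed to vary like the others. Labelling protocol was a fixed block in both fits. Every probe set of PTK2, the gene of focal adhesion kinase (FAK), was also tested by an exact two-sided permutation test of the difference of means, over the 36 arrangements within labelling protocols and over all 70. Its 95% interval came from the limma fit.

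Before the data were examined, 23 gene lists were fixed: focal adhesion, estrogen response, luminal epithelial, mesenchymal, basal and myoepithelial, fibroblast, haematopoietic and endothelial genes, proliferation, p53 targets, apoptosis regulators, interferon response, NF-kB and inflammation, ERK output, YAP targets, hypoxia and glycolysis, cholesterol synthesis, ER stress with the integrated stress response, heat shock, Wnt targets, growth factor receptors with their signalling genes, ribosomal proteins and mitochondrial respiration. Of their 688 members 625 were measured, counting a gene once per list. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, which compares a list with all other genes, with adjustment over the 23 lists, for FAKsiRNA against all controls and against vector control. Calls of members were counted over all genes tested and adjusted over the list alone. Camera with an estimated correlation and fry, which tests a list by itself, were alternatives.

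The genes named were chosen by a rule also fixed before the data were examined. For FAKsiRNA against all controls it takes the 12 largest rises and 12 largest falls among called genes in which, within each labelling protocol, both FAKsiRNA arrays lie beyond both control arrays, and whose higher arm has a mean at or above the median of all probe set means (5.65 log2). Places not filled by called genes go to the smallest p under the other conditions. The rule takes 8 and 8 genes against vector control, and 4 and 4 in each other comparison. In each list it takes up to 4 called members with the smallest p, or the 2 members with the smallest p. PTK2 is always named. Unnamed, hypothetical and multi-symbol loci are passed over.

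The fits were checked on simulated data with the arrays' own spread for 19775 genes, with noise drawn independently for each gene. For FAKsiRNA against all controls, 35.8%, 88.1% and 98.5% of the genes changed by 0.5, 1 and 2 log2 were recovered, with 12 false calls. For FAKsiRNA against vector control the shares were 37.3%, 80.6% and 95.5%, with 8 false calls. A shift of 0.3 log2 in the proliferation list was recovered in both, with 0 other lists past the threshold. Genes of a list were uncorrelated in this simulation, while the estimated correlation of the proliferation list was 0.597 in the data against all controls. The simulation therefore does not show how often lists pass falsely in these data.

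Alternatives fixed before the data were examined were no labelling block, labelling as a random block, each labelling protocol by itself, quantile normalization, centring of arrays on their medians, the upper part of genes by mean level, the mean of all probe sets of a gene, an intensity trend in the prior variance, an unadjusted p under 0.05 with a fold of at least 1.5, controls without plain MCF-7, and leaving out each array in turn. Dominant-negative FAK and FAK-CD, which the series title names, were not analysed here.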

Results

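Expression was compared between MCF-7 cells carrying FAKsiRNA (4 arrays) and control cells of 3 kinds: vector control (2 arrays), siRNA control (1 array) and plain MCF-7 (1 array). FAK is a tyrosine kinase that acts at integrin adhesions, and the series title places these lines in a study of FAK in the tumorigenesis of MCF-7 cells. Arrays separated first by labelling protocol. The protocols also differ in RNA input and in the kinds of control they hold, and these cannot be told apart here. The first principal component held 44.9% of the variance and parted the standard Affymetrix arrays from the MessageAmpII arrays, and 5975 genes differed between the protocols at an adjusted p under 0.05 in the fit of 2 arms. Each protocol held 2 FAKsiRNA and 2 control arrays, and the protocol was a block in every comparison below. As a sign of RNA integrity, the 3' minus 5' difference lay between -0.11 and 0.07 log2 for GAPDH and between 0.04 and 0.25 log2 for ACTB over the 8 arrays.

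PTK2 mRNA, the siRNA target, was measured first. On the probe set that stands for the gene (208820_at) it was 10.13, 9.77, 10.52 and 10.12 log2 on FAKsiRNA arrays 1 to 4, against 9.84 and 10.22 on the vector control arrays, 10.31 on the siRNA control array and 10.21 on the plain MCF-7 array. The means were 10.13 ± 0.31 (SD, n = 4) and 10.14 ± 0.21 (SD, n = 4). The difference was -0.01 log2 with a 95% interval from -0.32 to 0.29, that is 0.803-fold to 1.23-fold, and the exact permutation test within labelling protocols gave p = 1, where the smallest p this design allows is 0.0556. Against vector control, siRNA control and plain MCF-7 the PTK2 difference was 0.10, 0.01 and -0.26 log2, and none passed the test. Of the gene's other probe sets, 207821_s_at differed by -0.12 log2, 241453_at by -0.26 log2 and the dimmer 1559529_at by -0.54 log2, with exact permutation p of 0.444, 0.0556 and 0.167 within protocols. Against all controls the interval of 241453_at, from -0.52 to -0.0055 log2, was the only 1 of the 4 that excluded 0. Against vector control 1559529_at differed by -0.80 log2 (SE 0.12, unadjusted p = 0.000286). The mean of all PTK2 probe sets differed by -0.24 log2, which did not pass either. By the main probe set PTK2 mRNA was therefore not lower on the arrays labelled FAKsiRNA. On 1559529_at it was lower than in vector control, but the siRNA control array (5.22 log2) lay below all 4 FAKsiRNA arrays (5.41 to 6.15). On 241453_at the difference from vector control was -0.15 log2 (SE 0.088, limma unadjusted p = 0.131). Protein was not measured on these arrays, and the directions below are those of arrays by their labels.

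**Figure D1:**
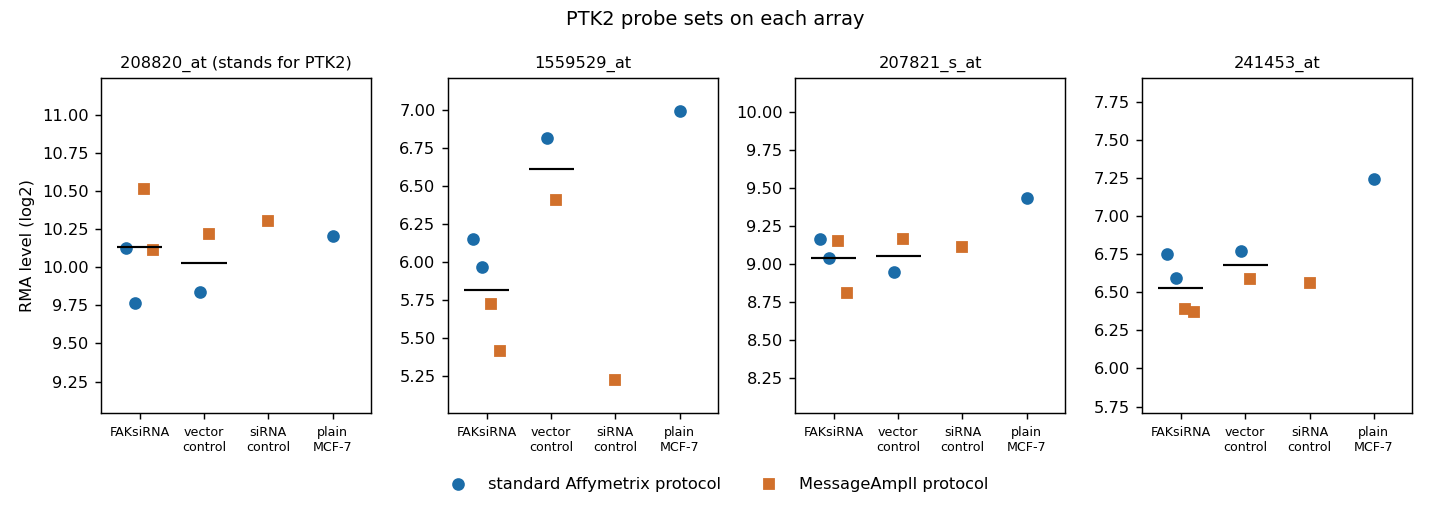
Level (RMA, log2) of the 4 PTK2 probe sets on each of the 8 arrays, by group; circles are arrays of the standard Affymetrix protocol, squares those of the MessageAmpII protocol, and lines are means of groups with more than 1 array. On 208820_at the FAKsiRNA arrays lie between 9.77 and 10.52 log2, around the 4 control arrays.

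The number of genes called differed widely between comparisons. The fit against all controls counts differences between kinds of control as spread, so its count is not on the same footing as the others. Against all controls together 3 genes were higher and 0 lower on the arrays labelled FAKsiRNA, against vector control 38 higher and 42 lower, against the siRNA control 79 and 68, and against plain MCF-7 697 and 705. The controls also differed from each other: siRNA control against vector control gave 278 higher and 237 lower genes, and vector control against plain MCF-7 gave 85 and 180.

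**Figure D2:**
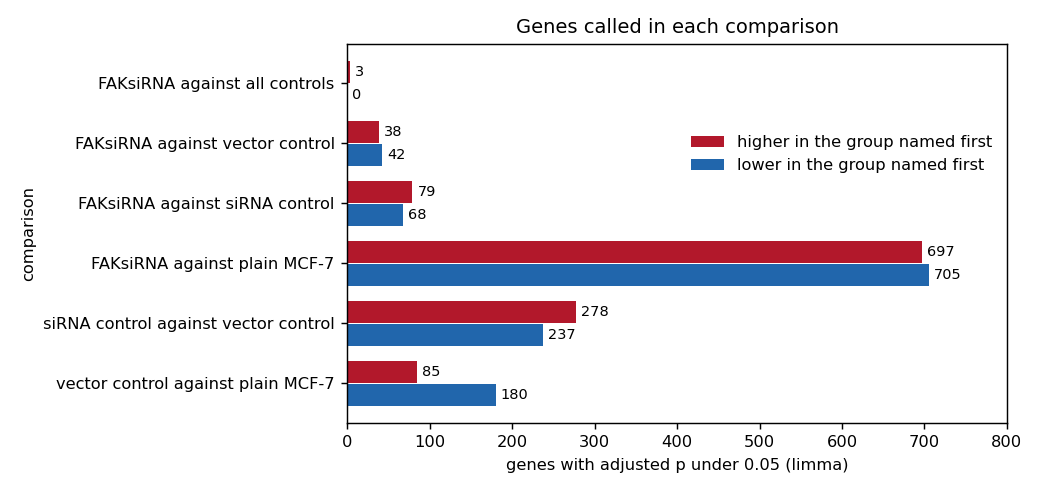
Number of genes with an adjusted p under 0.05 in limma (horizontal axis) in each of the 6 comparisons (vertical axis), higher in red and lower in blue in the group named first. The bars run from 0 lower genes in FAKsiRNA against all controls to 705 in FAKsiRNA against plain MCF-7.

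The first comparison sets the mean of the FAKsiRNA arrays against the pooled mean of the 4 control arrays, not against each control. The 3 genes that rose were SPOCK1, a secreted proteoglycan of the extracellular matrix, GNB4, a G protein beta subunit, and ZNF300, a zinc finger protein. SPOCK1 (202363_at) was 1.34 log2 higher (2.53-fold, SE 0.12, adjusted p = 0.0143), with means of 7.22 on 4 FAKsiRNA arrays and 5.89 on 4 controls. GNB4 (225710_at) was 1.23 log2 higher (2.34-fold, SE 0.11, adjusted p = 0.0143). ZNF300 was 1.38 log2 higher (SE 0.10, adjusted p = 0.00909) at a level too low for the naming rule, and is named here after its values were seen because so few genes passed. For all 3, each FAKsiRNA array lay above each control array of its labelling protocol, which the rule requires of SPOCK1 and GNB4.

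The rule itself requires that the arrays of the arms do not overlap within a protocol, so the lack of overlap adds no support. The other genes the rule names did not pass the test after adjustment. On the higher side these were TIMP2, an inhibitor of matrix metalloproteinases (1.15 log2), PSG4, a pregnancy-specific glycoprotein (1.09), the transcription factor ATOH8 (1.32), RGS22 (1.56), the long noncoding RNA NRAD1 (2.36), BPGM, which makes the haemoglobin effector bisphosphoglycerate (1.62), ARHGEF37 (0.68), the Notch target HEY1 (0.61), IGFBP3, which binds insulin-like growth factors (1.05), and CGA, the shared alpha chain of the glycoprotein hormones (1.13). Their adjusted p ran from 0.0623 to 0.106. On the lower side stood LINC00052 (-0.81 log2, adjusted p = 0.0841), FBXO15 (-0.61), RAMP1, a partner of the calcitonin receptor-like receptor (-1.02), the small GTPase RAB39B (-1.23), the farnesyltransferase subunit FNTB (-0.98), ANKRD18A (-1.10), DICER1-AS1 (-0.44), HEY2, a paralog of HEY1 (-0.84), EOLA2 (-0.58), the tetraspanin TSPAN4 (-0.39), LRIG2 (-0.55) and CREB3L4 (-0.43), with adjusted p up to 0.168. Of 10 other probe sets above the level floor that belong to the 24 genes named by rule, 10 went the same way. With those below the floor included, 17 of 19 did, and CGA's only other probe set went the opposite way. Several of the 24 genes, SPOCK1, RGS22, NRAD1 and BPGM among them, have no other probe set. RGS22, NRAD1 and CGA lay below the level floor in the controls, so the size of their differences is uncertain. PSG4, ANKRD18A and EOLA2 have near-identical paralogs, and their values are uncertain for that reason.

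**Figure D3:**
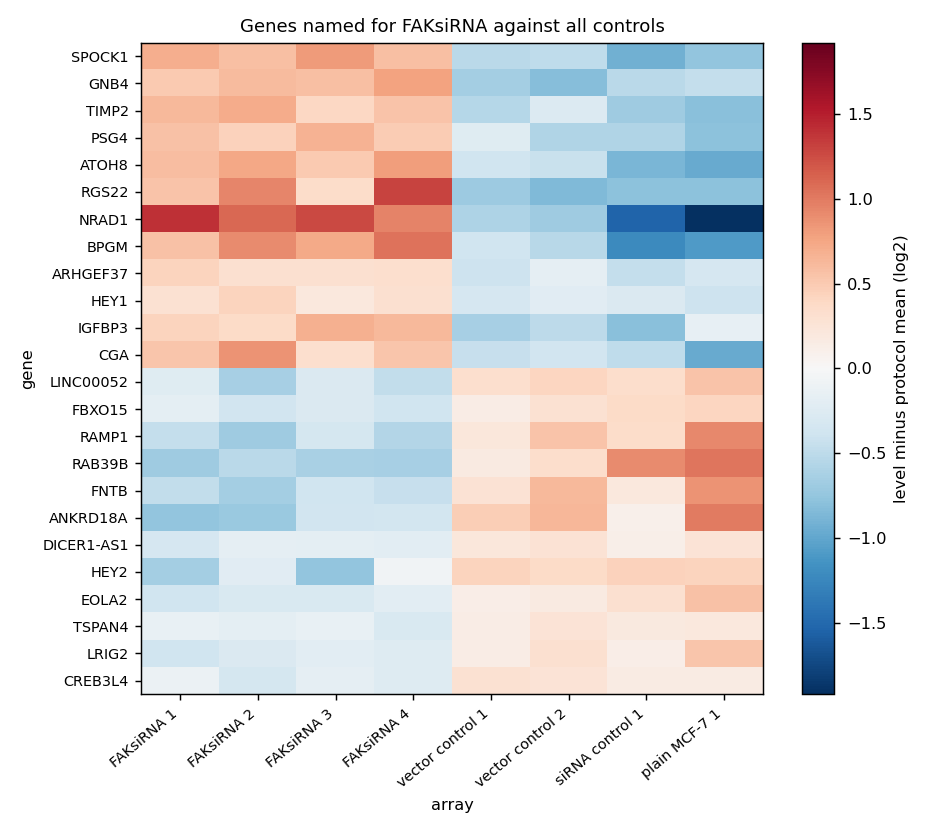
Level of each of the 24 genes named by rule for FAKsiRNA against all controls (rows) on each of the 8 arrays (columns), as the difference from the mean of the array's labelling protocol in log2 (colour). Only SPOCK1 and GNB4 of these passed the adjusted test; NRAD1 has the widest range.

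At an unadjusted p under 0.05, 1605 genes were higher and 842 lower, where about 989 in all would be so by chance. The limma count depended on single arrays: it was 0 without FAKsiRNA array 2, 1 without FAKsiRNA array 1 or 4, and 6 without FAKsiRNA array 3. Over 17 other settings SPOCK1 stayed between 1.24 and 1.41 log2 and passed in 8, and ZNF300 stayed between 1.27 and 1.49 and passed in 13. GNB4 passed in 9, and its difference was 0.59 log2 with the mean of all probe sets (adjusted p = 0.08). Without the siRNA control array the count of called genes was 104 (36 higher and 68 lower), and with no labelling block 0.

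Among the fixed lists, 7 were set apart from other genes by camera against all controls, and no list passed with an estimated correlation. The fibroblast list lost its call under that setting although its estimated correlation was -0.035, below the preset 0.01. The size of the correlation therefore does not by itself account for the loss of calls. Proliferation genes stood higher, with a median of 0.30 log2 and 47 of 47 measured members above 0 (adjusted p = 9.24e-06, and adjusted p = 0.763 with an estimated correlation). No member passed over all genes and 1 passed adjusted over the list alone; the members with the smallest p were CCNE2, a cyclin of S phase entry (0.60 log2, SE 0.090), and UHRF1, which maintains DNA methylation (0.42 log2, SE 0.098). This shift was uneven between protocols: the median was 0.57 log2 within the standard arrays (adjusted p = 1.15e-12) and -0.00 within the MessageAmpII arrays (adjusted p = 0.378), where the siRNA control array stood 0.27 log2 above its protocol's mean. It was 0.10 log2 without the plain MCF-7 array, whose list mean lay -0.54 log2 from its protocol's mean, and 0.48 without the siRNA control array.

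Genes of ER stress and the integrated stress response stood lower on the arrays labelled FAKsiRNA, with a median of -0.18 log2 and 21 of 29 members below 0 (adjusted p = 2.16e-07, and adjusted p = 0.218 with an estimated correlation). No member passed over all genes, and 5 were lower adjusted over the list alone. The smallest p belonged to the ER chaperones HSP90B1 (-0.34 log2, SE 0.077) and PDIA4 (-0.30 log2, SE 0.070). The median was -0.16 log2 within the standard arrays (adjusted p = 3.93e-05) and -0.20 within the MessageAmpII arrays (adjusted p = 1.54e-05). Array means of the list lay -0.16 and -0.20 log2 from the protocol mean on FAKsiRNA arrays 1 and 3, and -0.04 and -0.06 on arrays 2 and 4. They were 0.06 and 0.01 on vector control arrays 1 and 2, 0.14 on plain MCF-7 and 0.25 on the siRNA control array.

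Mesenchymal genes had a median of 0.12 log2 (31 of 38 above 0, adjusted p = 0.0409, and adjusted p = 0.659 with an estimated correlation), with 3 higher and 1 lower adjusted over the list alone. IGFBP3 (1.05 log2) and TWIST1, a transcription factor of epithelial-mesenchymal transition (-0.74 log2), had the smallest p and opposite signs. The interferon response list had a median of 0.13 log2 (33 of 47 above 0, adjusted p = 0.0148, and adjusted p = 0.763 with an estimated correlation), led by IFI44 (0.46) and IFIT3 (0.33). Within the standard arrays neither passed, at 0.16 and 0.15 log2 (adjusted p of 0.231 and 0.172), while within the MessageAmpII arrays both did, at 0.12 and 0.13 log2 (adjusted p of 0.0229 and 0.000812). Array means for the interferon list were 0.27 and 0.30 log2 above the protocol mean on FAKsiRNA arrays 1 and 3, and -0.08 and -0.06 on arrays 2 and 4. The mesenchymal median was 0.07 log2 without plain MCF-7, and the list no longer passed without the siRNA control array (adjusted p = 0.195) or FAKsiRNA array 2 or 3 (0.0745 and 0.0871). The interferon list no longer passed without the siRNA control array (adjusted p = 0.166) or FAKsiRNA array 1 or 3 (0.106 and 0.228).

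Among markers of other cell types, fibroblast genes had a median of 0.16 log2 (12 of 16 above 0, adjusted p = 0.0301, and adjusted p = 0.412 with an estimated correlation), with DCN at 0.36 and COL3A1 at 0.35 log2. Haematopoietic genes had a median of 0.14 log2 (17 of 17 above 0, adjusted p = 0.0224, and adjusted p = 0.763 with an estimated correlation), with CD2 at 0.32 and ITGB2 at 0.18 log2. Of these lists 9 of 16 and 8 of 17 members lay below the level floor. Within the standard arrays the medians were 0.14 and 0.18 log2 (adjusted p of 0.197 and 0.0634), and within the MessageAmpII arrays 0.12 and 0.11 log2 (adjusted p of 0.0188 and 0.188). Ribosomal protein genes stood slightly lower, at a median of -0.03 log2 (26 of 29 below 0, adjusted p = 0.015, and adjusted p = 0.763 with an estimated correlation), with RPL19 and RPLP1 each at -0.13. Their median was -0.06 within the standard arrays (adjusted p = 0.00766) and -0.01 within the MessageAmpII arrays (adjusted p = 0.378). Leaving out 1 array also ended calls here. The fibroblast list did not pass without the siRNA control array (adjusted p = 0.138) or FAKsiRNA array 3 (0.0871). The haematopoietic list did not pass without plain MCF-7 (0.11), vector control array 2 (0.0791) or FAKsiRNA array 1 or 3 (0.0767 and 0.0871). The ribosomal list did not pass without plain MCF-7 (0.0513), vector control array 2 (0.181) or FAKsiRNA array 2 (0.0728).

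The other 16 lists did not pass against all controls, with adjusted p from 0.154 to 0.968. Focal adhesion genes had a median of 0.04 log2 with 27 of 48 above 0, led by FERMT2 (0.39) and ZYX (0.36). Of these members 1 was higher adjusted over the list alone and 0 over all genes. Estrogen response genes had a median of 0.04 but a mean of -0.12 log2, with RAPGEFL1 at -0.44 and CXCL12 at 0.73. The medians were -0.04 for luminal genes (CLDN3 -0.43, OVOL1 0.33), 0.02 for basal genes (TRIM29 0.41, GABRP -1.10), 0.07 for endothelial genes (TEK 0.32, EMCN -0.68), 0.02 for p53 targets (APAF1 -0.33, PMAIP1 0.72) and 0.02 for apoptosis regulators (BNIP3L 0.59, CASP8 0.44). They were 0.07 for NF-kB genes (TNF 0.25, ICAM1 0.28), 0.06 for ERK output (PHLDA1 1.39, EPHA2 0.46), 0.10 for YAP targets (ANKRD1 1.26, TGFB2 0.72), -0.03 for hypoxia and glycolysis (ANKRD37 -0.54, NDRG1 0.26) and 0.07 for cholesterol synthesis (INSIG1 0.38, SC5D 0.38). The rest had medians of -0.04 for heat shock (DNAJB1 0.30, BAG3 0.43), 0.11 for Wnt targets (AXIN2 0.30, BMP4 -0.22), 0.05 for growth factor receptors (KIT 3.79, EPHA2 0.46) and -0.00 for mitochondrial respiration (COX6C 0.18, NDUFB5 0.18). Camera's direction, which is relative to other genes, was downward for the luminal, basal, p53, apoptosis, heat shock and mitochondrial lists although their means lay above 0. The median of all genes was 0.03 log2.

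**Figure D4:**
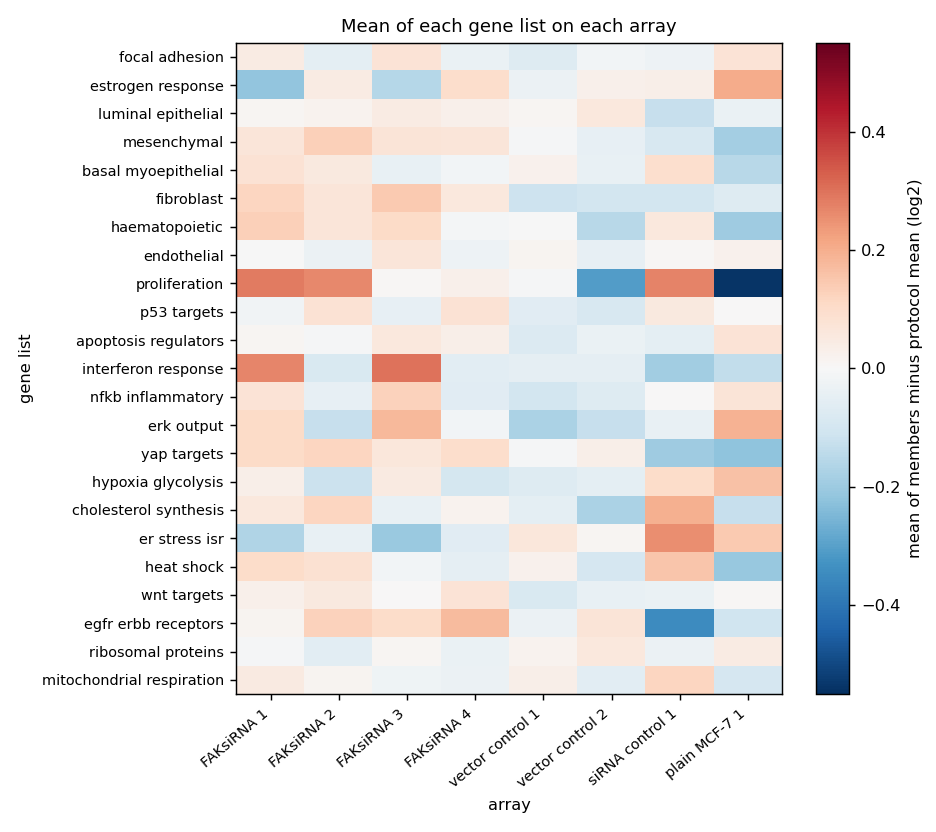
Mean of each of the 23 gene lists (rows) on each of the 8 arrays (columns), as the difference from the mean of the array's labelling protocol in log2 (colour). The proliferation list runs from -0.54 on the plain MCF-7 array to 0.28 on FAKsiRNA array 1, with 0.27 on the siRNA control array.

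Vector control cells are the only control measured under both labelling protocols. Against them the arrays labelled FAKsiRNA (4 against 2) had 38 genes that rose and 42 that fell, 26 of them by more than 2-fold. The test takes these arrays as independent, although the labels do not say whether arrays share a line. Genes the rule names on the higher side were the long noncoding RNA NRAD1 (1.81 log2, 3.51-fold, SE 0.13, adjusted p = 0.0129), GNB4 (1.35 log2), the iron-siderophore carrier LCN2 (1.33), the hair keratin-associated gene KRTAP4-1 (1.30), BPGM (1.27), the class IIa histone deacetylase HDAC9 (1.22), SPOCK1 (1.17) and the secreted NELL2 (1.12). On the lower side they were LCA5L (-1.84 log2, 3.59-fold, SE 0.12, adjusted p = 0.0129), the pseudogene MICOS10P1 (-1.22), GTF2H2B (-1.19), the transcription factor SOX6 (-1.14), EIF3C (-1.12), ANKRD18A (-1.10), ZNF518A (-1.06) and MIA2 (-1.005). Adjusted p of these 16 genes ran from 0.0129 to 0.0487. LCN2, KRTAP4-1 and HDAC9 lay below the level floor in vector control, and MICOS10P1, EIF3C and MIA2 did on the arrays labelled FAKsiRNA, so the size of these differences is uncertain. MICOS10P1, GTF2H2B, EIF3C, ANKRD18A and KRTAP4-1 have near-identical relatives and are uncertain. At an unadjusted p under 0.05, 2078 genes were higher and 956 lower. The count of called genes was 0 without FAKsiRNA array 2 or 4, and 0 without either vector control array, which left the lone vector array to be judged by the spread of other groups. It was 17 and 21 without FAKsiRNA arrays 1 and 3, 50 with the mean of all probe sets, 0 with no labelling block and 0 within each labelling protocol by itself.

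Members of the fixed lists that passed over all genes against vector control were IGFBP3 (1.09 log2, SE 0.074) and the matrix protein TGFBI (0.70, SE 0.075) among mesenchymal genes, KRT15 (-0.67, SE 0.074) among basal genes, the ERK phosphatase DUSP4 (0.66, SE 0.078), the YAP target ANKRD1 (1.35, SE 0.16) and the stress transcription factor ATF3 (0.74, SE 0.087), with adjusted p from 0.0129 to 0.0421. Proliferation genes stood higher, with a median of 0.32 log2 and 46 of 47 members above 0 (adjusted p = 3.45e-15, and adjusted p = 0.119 with an estimated correlation). None passed over all genes and 33 were higher adjusted over the list alone, led by UHRF1 (0.49 log2, SE 0.069) and the mitotic kinase AURKA (0.44, SE 0.071). The proliferation median was 0.30 within the standard arrays and 0.34 within the MessageAmpII arrays. Each of these sets FAKsiRNA arrays against a lone vector control array, and the protocols may hold the same lines. They are therefore not independent repeats. The estimated correlation of the list against vector control was 0.018, near the preset 0.01.

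The ER stress list stood lower than in vector control at a median of -0.17 log2 (19 of 29 below 0, adjusted p = 3.11e-06, and adjusted p = 0.18 with an estimated correlation). The list's median was -0.16 within the standard and -0.17 within the MessageAmpII arrays, each against a lone vector control array. Its 1 member called over all genes, ATF3, rose, while 5 were lower and 1 higher adjusted over the list alone; HSP90B1 stood at -0.38 log2 and did not pass. Ribosomal protein genes had a median of -0.06 log2 (27 of 29 below 0, adjusted p = 0.000604, and adjusted p = 0.519 with an estimated correlation), with RPL38 at -0.14 and RPL3 at -0.16. Their medians were -0.05 within each protocol, again against a lone vector control array.

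The other 20 lists did not pass against vector control, with adjusted p from 0.0721 to 0.811. Among them were focal adhesion genes (median 0.07 log2, FYN 0.51, FERMT2 0.38), estrogen response genes (0.01, with TFF3 -0.65 and SERPINA3 -0.77, and 6 lower and 1 higher adjusted over the list alone), luminal genes (-0.04, SCUBE2 -0.69, OVOL1 0.37), mesenchymal genes (0.09, 5 higher and 3 lower adjusted over the list alone), basal genes (0.05) and ERK output (0.13, SPRY1 0.47). Markers of other cell types had medians of 0.16 for fibroblast (DCN 0.42, MFAP5 0.39), 0.16 for haematopoietic (CD2 0.38, FCER1G 0.22) and 0.10 for endothelial genes (EMCN -0.86, TEK 0.27). Medians were 0.08 for p53 targets (GDF15 0.49, PMAIP1 0.86), 0.07 for apoptosis regulators (DAPK1 0.43, CASP8 0.50), 0.14 for interferon (ISG20 0.58, IFIT3 0.37), 0.15 for NF-kB (IL1A -0.72, TNFAIP3 0.66), 0.10 for YAP targets (TGFB2 0.48), 0.03 for hypoxia (NDRG1 0.35, ANKRD37 -0.51) and 0.17 for cholesterol synthesis (INSIG1 0.50, STARD4 0.65, 5 members higher adjusted over the list alone). They were 0.03 for heat shock (CHORDC1 0.36, DNAJB1 0.29), 0.05 for Wnt targets (AXIN2 0.48, LGR5 0.29), 0.01 for growth factor receptors (FGFR1 -0.53, EPHA2 0.48) and 0.02 for mitochondrial respiration (NDUFS1 0.18, NDUFA9 0.17). Camera's direction was downward for the basal, hypoxia, growth factor receptor and mitochondrial lists although their means lay above 0, and for the estrogen list, whose median lay above 0 and whose mean was -0.06. The median of all genes was 0.05 log2.

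The siRNA control, a line with an siRNA against luciferase, controls for siRNA expression itself. Against its 1 array, 79 genes were higher and 68 lower on the arrays labelled FAKsiRNA, 87 of them by more than 2-fold. The luminal transcription factor TFAP2A (AP-2 alpha) was 4.02 log2 higher (SE 0.29, adjusted p = 0.0111), the xenobiotic-metabolising enzyme CYP1A1 3.69 log2 higher (SE 0.49, adjusted p = 0.044), the death ligand TNFSF10 (TRAIL) 3.07 and BRINP3 3.04. The retrotransposon-derived PEG10 fell by 3.57 log2 (SE 0.42, adjusted p = 0.0346), with the kisspeptin receptor KISS1R at -3.16, the cytokine IL20 at -2.59 and the calcium-binding S100A2 at -2.07. Each of these but S100A2 lay below the level floor on 1 side, so the size of their differences is uncertain. The siRNA control array itself differed from vector control in the mirrored direction at TFAP2A (-3.53 log2), TNFSF10 (-3.01), KISS1R (3.38), IL20 (2.49) and S100A2 (2.32). At these genes the difference therefore lies largely with the siRNA control array. Of the ER stress list 2 members fell, DDIT3 (-1.52) and NUPR1 (-1.34), with 7 lower and 1 higher adjusted over the list alone. Of the mesenchymal list IGFBP3 (1.43), CD44 (1.15) and TGFBI (0.92) rose, and of the estrogen list the serpins SERPINA1 (-1.84) and SERPINA3 (-1.49) fell. DUSP4 (0.96) and SPRY1 (0.90), feedback inhibitors of ERK signalling, rose, as did KRT15 (0.82). Against vector control (-0.67) and plain MCF-7 (-0.76), however, KRT15 was lower on the arrays labelled FAKsiRNA. The mean of the proliferation list was -0.26 log2, opposite in sign to the comparison with vector control, with 1 member lower over all genes and 21 lower and 2 higher adjusted over the list alone. The count of called genes was 0 without either vector control array, and 57, 29, 27 and 11 without FAKsiRNA arrays 1, 2, 3 and 4. Testing only genes in the upper part by level gave 575, an intensity trend gave 377 and no labelling block gave 27. After centring arrays on their medians the split was 84 higher and 102 lower.

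Against plain MCF-7 (4 arrays against 1), the arrays labelled FAKsiRNA gave the most called genes: 697 rose and 705 fell, 408 by more than 2-fold. The zinc finger gene ZNF738 was 5.82 log2 higher (SE 0.67, adjusted p = 0.0115), the receptor tyrosine kinase KIT 4.82 (SE 0.79, adjusted p = 0.0271), the secreted CCN5 4.77 (SE 0.17, adjusted p = 0.000579) and TFAP2A 4.31 (SE 0.29, adjusted p = 0.00317). On the lower side the rule names LCN2 (-3.86 log2, SE 0.19, adjusted p = 0.00225), the kynurenine pathway enzyme KMO (-3.63), NIBAN1 (-3.04) and PEG10 (-3.02). Of these 8 genes all but CCN5 and LCN2 lay below the level floor on 1 side, so the size of their differences is uncertain. Vector control differed from plain MCF-7 in the same direction at ZNF738 (4.91 log2), CCN5 (4.25), TFAP2A (3.83), LCN2 (-5.18) and KMO (-3.67). These differences are therefore not particular to the arrays labelled FAKsiRNA, where LCN2 was 1.33 log2 higher than in vector control. The mean of the proliferation list was 0.82 log2 here and 0.52 for vector control against plain MCF-7. Of the proliferation list 32 of 47 members were called higher and 0 lower, and 38 were higher adjusted over the list alone, among them PTTG1 (1.62), AURKA (1.46), CCNA2 (1.39) and PLK1 (1.49). In the mesenchymal list 9 rose and 2 fell, among them SNAI2 (2.38), LOXL2 (1.56), PLAU (0.91) and TGFBI (-0.93). In the estrogen list 6 fell and 2 rose, and the 4 with the smallest p were TFF3 (-2.24), SERPINA1 (-2.15), PDZK1 (-2.60) and SERPINA3 (-2.60).

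Other lists held fewer called genes against plain MCF-7. In the interferon list 7 rose, with SAMD9 at 2.13 and IFI6 at 1.29, and 4 YAP targets rose (TGFB2 1.35, DLC1 1.52, ANKRD1 1.504, NT5E 2.66). In the ER stress list NUPR1 (-2.00), SEL1L (-0.67) and DDIT3 (-0.73) fell and ATF3 (0.84) rose. In the focal adhesion list CAPN2 (-1.99) fell and ILK (0.57) and FERMT2 (0.50) rose. The hypoxia genes VEGFA (-1.01) and ADM (-1.47) fell while LDHA (0.69) and HK1 (0.54) rose. The heat shock genes FKBP4 (0.70), CHORDC1 (0.61) and BAG3 (1.08) rose. Among haematopoietic genes CORO1A (1.18) and CD2 (0.57) rose and none fell, with a list mean of 0.31 log2. Of the basal list 3 rose and 2 fell, with ID4 at 2.74, CAV2 at 1.27, KRT15 at -0.76 and OXTR at -0.64. Of the luminal list 2 rose and 3 fell, with TFAP2A at 4.31, PRSS8 at -0.70, ELF3 at -0.66 and SCUBE2 at -0.88. Growth factor receptors rose in KIT (4.82) and EPHA2 (0.65) and fell in FGFR1 (-0.77) and INSR (-1.30). The p53 targets FAS (0.81) rose and GDF15 (-0.78) and TP53INP1 (-0.85) fell, and of ERK output DUSP5 (-1.42) fell and EPHA2 rose. The number of called genes was 98 without either vector control array, 675, 299 and 897 without FAKsiRNA arrays 1, 2 and 4, and 234 with no labelling block.

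The controls were also compared with each other. An arm of 1 array cannot part a difference between lines from one between single arrays or cultures, here as in the comparisons with siRNA control and plain MCF-7 above. The siRNA control differed from vector control at 278 genes higher and 237 lower (1 array against 2). KISS1R was 3.38 log2 higher (SE 0.26, adjusted p = 0.0137), IL20 2.49, the mammary gene MUCL1 2.48 and GPNMB 2.36, and on the lower side the rule names TFAP2A (-3.53 log2, SE 0.31, adjusted p = 0.0178), the connexin GJA1 (-3.37), TNFSF10 (-3.01) and the noncoding RNA MALAT1 (-2.34). KISS1R, IL20, TFAP2A, GJA1 and TNFSF10 lay below the level floor on 1 side, so the size of their differences is uncertain. Of the proliferation list 17 of 47 members were called higher in the siRNA control, and 30 adjusted over the list alone (CENPF 1.14, KIF20A 0.98, BIRC5 0.96, PTTG1 0.91). DDIT3 (1.097) and ATF3 (1.07) were higher, as were the cholesterol synthesis genes ACAT2 (0.97) and STARD4 (1.14), and IRS2 (-1.12), ERBB4 (-0.999) and FGFR1 (-0.72) were lower. After centring arrays on their medians the split was 435 higher and 227 lower, and the median of all genes moved from 0.08 to 0.13 log2. The count was 0 without either vector control array, between 33 and 143 without any one FAKsiRNA array, 34 with no labelling block and 991 among genes in the upper part by level.

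Vector control differed from plain MCF-7 at 85 genes higher and 180 lower (2 arrays against 1). ZNF738 was 4.91 log2 higher (SE 0.73, adjusted p = 0.0436), CCN5 4.25, TFAP2A 3.83 and the secreted lectin REG4 3.55, and on the lower side the rule names LCN2 (-5.18 log2, SE 0.20, adjusted p = 0.0013), KMO (-3.67), GPNMB (-3.62) and the keratin KRT20 (-2.93). All of these but CCN5 and GPNMB lay below the level floor on 1 side, so the size of their differences is uncertain. Of the proliferation list 10 members were higher (PTTG1 1.37, PLK1 1.15, CCNA2 0.997, AURKA 1.02) and 29 adjusted over the list alone. In the estrogen list SERPINA1 (-2.10), TFF3 (-1.59), PDZK1 (-1.95) and SERPINA3 (-1.83) were lower, and in the mesenchymal list SNAI2 (2.22) and LOXL2 (1.01) were higher and TGFBI (-1.63) lower. The count was 0 and 7 without vector control arrays 1 and 2, between 50 and 146 without any one FAKsiRNA array, and 48 with no labelling block.

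The FAKsiRNA arrays themselves fell apart in a way that recurred under both labelling protocols. Across the 19775 genes, the difference of FAKsiRNA array 1 minus 2 (standard protocol) correlated with that of array 3 minus 4 (MessageAmpII) at Pearson r = 0.732 and Spearman rho = 0.574; genes are not independent replicates. At 154 genes both differences reached 1 log2, and at 153 of them they had the same sign. ATP6V0D2, a proton pump subunit, differed by 3.52 and 3.89 log2, PSAT1, an enzyme of serine synthesis, by 2.14 and 2.53, TXNIP, an inhibitor of thioredoxin, by -2.64 and -2.62, and the secreted STC1 by -2.57 and -2.47. These genes were chosen after their values were seen, from those with the largest differences under both protocols. The labels do not say which FAKsiRNA arrays share a line, and all 4 were kept as 1 group.

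**Figure D5:**
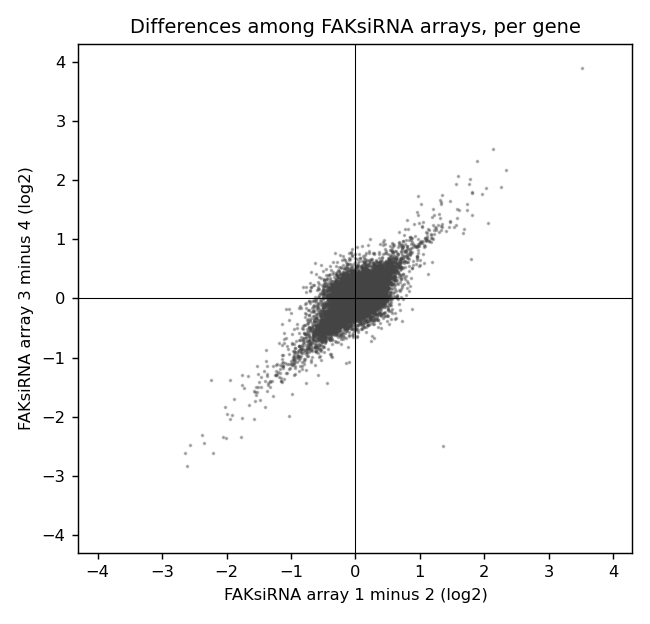
Each point is 1 of 19775 genes; the horizontal axis is FAKsiRNA array 1 minus array 2 and the vertical axis array 3 minus array 4, both in log2. Points at the ends lie along the diagonal, with ATP6V0D2 at 3.52 and 3.89 log2.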

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

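Among the genes named in the report, 1 had a FAKsiRNA array far from the others. UHRF1, of the proliferation list, was 10.33 log2 on FAKsiRNA array 1, against 10.26 on the nearest of the other 3 arrays, a gap of 0.926 of the group's whole range. The group's range was narrow, and of 167 genes tested in this way about 8.35 would be set apart by chance, so no explanation was weighed.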

How the results depend on the processing

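Apart from PTK2, whose values follow below, no gene named in the report's comparisons between groups reversed under another setting except ITGB2 against all controls, which was 0.18 log2 and became -0.16 with the mean of all probe sets; neither passed, and the cause was not tested. Genes that passed kept their side of the threshold in 745 of 927 values over settings other than leaving out an array, and in 569 of 1096 values with an array left out. Genes called against all controls (3) became 0 with no labelling block, 8 with quantile normalization, 6 with arrays centred on their medians, 0 among genes in the upper part by level, 13 with a random block, 357 by unadjusted p and fold, 0 within the standard and 0 within the MessageAmpII arrays; at an unadjusted p under 0.05 those zero counts held 1217, 1400, 1498 and 618 genes. Against vector control (80) they became 0 with no block, 50 with the mean of all probe sets, 312 by unadjusted p and fold, and 0 within each protocol (1123, 793 and 961 at an unadjusted p under 0.05 without a block and within the standard and MessageAmpII arrays). With no block the remaining comparisons gave 27 (siRNA control), 234 (plain MCF-7), 34 (siRNA control against vector control) and 48 (vector control against plain MCF-7); by unadjusted p and fold they gave 1080 (siRNA control), 1452 (siRNA control against vector control) and 1113 (vector control against plain MCF-7). The upper part by level gave 575 and 991 for the siRNA control against FAKsiRNA and vector control, and an intensity trend 377 for the former. Fewer arrays or fewer genes enter some of these fits, and the other causes were not tested. With 1 array left out the counts ran from 0 to 104, 0 to 80, 0 to 147, 98 to 1402, 0 to 515 and 0 to 265 in the order of the report.

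The PTK2 difference against all controls (-0.01 log2) was 0.053 within the MessageAmpII arrays and 0.075 without plain MCF-7 among the controls, and ran from -0.10 to 0.075 with an array left out. Against vector control (0.10) it was -0.21 with the mean of all probe sets and 0.02 to 0.19 with an array left out. It passed the threshold in none of these. Lists past camera's threshold against all controls (7) numbered 4 with quantile normalization, 2 in the upper part by level, 4 with the mean of all probe sets, 3 within the standard and 4 within the MessageAmpII arrays, 0 with an estimated correlation, 1 by fry (the fibroblast list), and 3 to 8 with an array left out. Against vector control (3) they numbered 5 with the mean of all probe sets, 5 within the MessageAmpII arrays, 0 with an estimated correlation, 4 by fry (4 higher and 0 lower) and 3 to 8 with an array left out. By fry the ER stress and ribosomal lists did not pass (adjusted p of 0.118 and 0.151). The median of the ER stress list stayed between -0.23 and -0.15 log2 against all controls, and that of the proliferation list between -0.00 and 0.57. No paired analysis was run, because the labels give the groups no shared replicate numbers beyond a single one. A block of arrays paired from their own values was not fitted either. RMA values carry no background call, so genes near the floor show compressed differences.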

Other observations

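Pregnancy-specific glycoproteins, normally made by the placenta, were a group outside the fixed lists, chosen after PSG4 was seen. Of 9 measured members 8 had a higher mean on the arrays labelled FAKsiRNA than on all controls, with a median of 0.68 log2 and a range from -0.01 to 1.27, although none passed by limma. PSG5 was 8.28, 7.47, 8.16 and 7.40 log2 on FAKsiRNA arrays 1 to 4, against 6.35 to 6.85 on the 4 controls. The probes of these near-identical paralogs cannot be taken as separate measurements.

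CYP1A1 and CYP1B1, targets of the aryl hydrocarbon receptor chosen after their values were seen, were low on the siRNA control array. CYP1A1 was 5.33 log2 there, against 8.01 and 8.06 on the vector control arrays, 7.85 on plain MCF-7 and 8.50 to 9.55 on FAKsiRNA arrays. CYP1B1 was 9.63 log2 there and at least 11.77 on each other array, and was lower in the siRNA control than in vector control by limma (-2.17 log2, SE 0.13, adjusted p = 0.0114). TFAP2A was low on both the siRNA control (5.42 log2) and plain MCF-7 (4.999 log2) and between 8.85 and 9.77 on the other 6 arrays. KIT was 3.53 log2 on the siRNA control and 3.99 on plain MCF-7, both below the level floor. It was 6.44 and 6.69 on vector control and 7.94 to 9.86 on FAKsiRNA arrays. No explanation of these was tested.

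The tests of exchanged labels, of the other PTK2 probe sets and of recurring differences among FAKsiRNA arrays were written only after the result was seen; those of an intensity trend, of other probe sets of called genes and of other splits were written before.

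PTK2 mRNA was not lower on the arrays labelled FAKsiRNA by the main probe set. An exchange of labels between FAKsiRNA and control arrays was predicted to leave some arrays of a protocol 1 log2 or more below the rest. The main probe set ranged over at most 0.443 log2 within a protocol, so that prediction was not met there. This range cannot decide about an exchange, since a probe set on which silencing does not show stays flat under any labels. On the dim 1559529_at the ranges were 1.02 and 1.18 log2. Among the standard arrays the lowest were those labelled FAKsiRNA, as the labels say. Among the MessageAmpII arrays both FAKsiRNA arrays lay below vector control (6.41 log2) but the siRNA control array was lowest (5.22). On 241453_at both lay below both controls of that protocol, as labelled. Deviations of the siRNA control array from the protocol mean correlated at 0.09 and -0.34 with FAKsiRNA arrays 1 and 2, against 0.53 for array 3 with 1 and 0.72 for array 4 with 2. These correlations would go against an exchange of the siRNA control array with FAKsiRNA array 3 or 4 only if arrays 1 and 3, and 2 and 4, share lines. That sharing is itself read from the same values, so the correlations cannot decide about the labels. A silenced transcript missed by the main probe set stays open: the intervals of 2 of the 3 other PTK2 probe sets exclude a fall of 1 log2, but that of 1559529_at runs from -1.11 to 0.02 log2. The interval of 241453_at, from -0.52 to -0.0055 log2, lies below 0, and its exact p of 0.0556 is the smallest the design allows. Against vector control 1559529_at differed by -0.80 log2 (SE 0.12) and 241453_at by -0.15 log2 (SE 0.088). An effect on the protein alone, or a loss of silencing in stable lines, could not be tested on these arrays.

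FAKsiRNA arrays 1 and 3, and 2 and 4, deviated together, with r = 0.732 between the difference of array 1 and 2 and that of array 3 and 4. This is consistent with the same cell lines having been labelled by both protocols, and as a hypothesis these may be the lines of the 2 FAK siRNAs that the design text names. An intensity trend shared by the arrays is argued against, since r was 0.734 after it was removed. Deviations from protocol means correlated at 0.53 for arrays 1 and 3 and 0.72 for 2 and 4, at 0.43 for the vector control arrays, and at -0.16 and -0.17 for the crossed FAKsiRNA arrays. Arrays of different controls also correlated, plain MCF-7 at 0.28 with the siRNA control array and at 0.19 with vector control array 2. If the same lines were labelled by both protocols, the group of 4 arrays holds 2 independent lines. The 2 vector control arrays may likewise be 1 line, which would make that comparison 2 lines against 1. The tests against controls and the splits of arrays would then overstate their replication.

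Genes called against vector control were checked on their other probe sets above the level floor, since a probe set that does not follow the gene's main transcript could give such calls. For genes called higher, 95.2% of other probe sets (20 of 21, from 14 of the 38 genes) went the same way. The exact 95% interval, from 76.2% to 99.9%, takes the probe sets of a gene as independent and still reaches below the bound of 80%, and the other genes have no such probe set, so this stays open. For genes called lower the share was 79.4% (27 of 34, from 21 of the 42 genes, 62.1% to 91.3%), and it stays open there too. The other probe sets moved less than the called ones, with medians of 0.41 and -0.21 log2 against 0.95 and -0.86.

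Chance could not be excluded for the 3 genes called against all controls: 2 of the 34 splits of the 8 arrays into 4 and 4 that could be fitted gave as many genes, the real one included, and the highest other split gave 5. That split set FAKsiRNA arrays 1 and 3 with plain MCF-7 and the siRNA control, so it keeps together FAKsiRNA arrays that deviate together. The split by labelling protocol could not be fitted with the protocol as a block. Of the 18 splits that divide each protocol evenly, as the real one does, 2 gave as many genes, the real one included. Nor could chance be excluded for the 7 lists past camera's threshold against all controls, as 8 of the 34 splits gave as many and the highest other split gave 11. Of the 18 even splits, 5 gave as many lists, the real one included.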
